A study of Mus musculus with 18 samples.

How the data were processed

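RNA was measured in 18 laser-captured lung metastases of AT3 cells, a mouse mammary carcinoma line derived from an MMTV-PyMT tumour. Per the labels' protocols, labelled AT3 cells were placed in the mammary fat pad of immunodeficient mice and spread to the lungs on their own. On day 11 the mice received either buffer or 60000 activated mouse NK cells by vein. Frozen lung sections were cut, lesions were chosen by their fluorescence and captured by laser, and 2 ng of total RNA per sample went into a library kit made for single cells. The labels give the strain as lacking Rag2 and Il2rg, while the growth protocol names Rag1 in place of Rag2. Strand handling is not given in the sources used here.

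Per the submitters' processing notes, bcl2fastq 2.17, STAR, RSEM 1.2.28 and DESeq2 were used with the mm10 build. The deposited gene table holds expected counts, the estimated counts that RSEM gives, with no scaling by the authors. They were rounded to whole numbers before any test. A second deposited table holds values on a log2 scale, as judged from the values, which the authors had normalized between samples. The transformation behind it is not given in the sources used here, and this table served only as an alternative. The deposited annotation table gives an animal number for each sample, and these numbers grouped the lesions into the same 5 hosts as the titles. There were 0 further columns of sample values.

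The titles name the host and the lesion. Hosts with NK cells are NK1 (3 lesions) and NK2 (4 lesions), and hosts that received buffer, labelled Ctrl, are KO1 (5 lesions), KO2 (4 lesions) and KO3 (2 lesions). A lesion is written as host and lesion number, so that NK1-3 is the lesion 3 of mouse NK1. Because lesions of a host are not independent, the mouse was the replicate, and counts were summed over the lesions of each mouse. Of 49585 gene identifiers, 49326 matched a symbol, and 26158 had any count. The filter filterByExpr of edgeR (minimum count 10, minimum total 15) kept 16917 genes.

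Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust, TMM scaling) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Values are CPM (counts scaled by the TMM-scaled library size), given as mean ± SD over mice. With 2 mice against 3, an exact permutation test cannot go below a one-sided p of 0.1, so p-values rest on a spread that the model shares between genes. That spread was wide, with a coefficient of variation of 64.9% for the common dispersion. In simulated data with the estimated dispersion, 14.9% of genes changed 4-fold were called, and 100% of those changed 16-fold or 64-fold, while 12 unchanged genes were called of 16917 simulated genes in all. The changed genes were drawn from those of higher expression, so these shares do not cover genes of few counts, such as most NK cell markers. In the data, Cyp2e1 did not pass at a log2 fold change of 8.97 (adjusted p = 0.9998), so the shares need not hold for these mice.

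The 21 gene lists (pathways and markers of cell types that a lung lesion could hold) were fixed before the data were examined, with 6 of them as primary. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 21 lists. Camera with a correlation estimated from the data and the rotation test fry stand beside it. In the simulation, a list of 20 genes raised 4-fold was called and 0 of 20 unchanged lists were. Its genes varied independently of each other, while the correlation estimated in the data reached 0.678 for neutrophils and 0.952 for red blood cells. The simulation therefore cannot show how often the preset correlation calls an unchanged list of that kind. A list score is the mean log2 CPM of its tested members.

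Named genes followed a rule fixed before the data were examined. It took in each direction the 10 genes with the smallest p, those past the threshold first, then in each list up to 4 members past the threshold or otherwise the 3 members with the highest mean count, and always Ncr1, Prf1, Gzmb, Il2rg, Rag2, Rag1, Krt14, Cdh1, Epcam and Vim. Of the genes the rule names, 3 are not reported here. Other genes are said to be chosen after their values were seen. Coordinates are 1-based positions on GRCm38 (mm10) from GENCODE M21. Genes with near-identical copies (Klra, Gzm, Hba, Hbb, H2 and Raet1 families) are uncertain, since reads can be split between copies, and genes that overlap on opposite strands are uncertain because strand handling is not given.

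Total counts ranged from 2964242 to 11798897 per lesion. Where a group held 0 counts, a fold was computed against a floor of 3 counts over the group and is a lower bound. Intervals and floors cover counting error only. No pair of lesions of a mouse agreed within sampling noise, since the lowest chi-square per degree of freedom was 23.8. Lesions of a host were compared with lesions of other hosts of the group by the mean Pearson correlation, with an exact one-sided permutation test of all arrangements.

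Alternatives comprised size factors of DESeq2, no filter on low counts, a filter of 10 counts in 9 lesions, equal weight per lesion, lesions as replicates, the mouse as a random block without and with a lung epithelium covariate, the normalized table, the host number as a replicate block, DESeq2 1.42.0, a threshold of 0.1, lists without shared members, and leaving out each mouse and each lesion. Added after seeing the data were DESeq2 on the genes that the edgeR filter kept, and fits without genes of ribosomal RNA, without the 6 lesions with over 40% of counts in mt-Rnr2, and without lesions NK1-1 and NK1-3. Figures were drawn with matplotlib 3.10.9. Labels give no batch or date, so none was examined.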

Results

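The study profiled AT3 lung metastases in mice that lack their own T, B and NK cells, with or without transferred NK cells, to characterize lesions that grew in either environment. There were 7 lesions from 2 mice with NK cells and 11 from 3 control mice. Total counts were 2964242 to 11798897 in the lesions with NK cells and 5690467 to 9816244 in the controls, and 13432 to 19173 genes had a count. A single transcript, the mitochondrial ribosomal RNA mt-Rnr2, took 12.1% to 68.7% of a lesion's counts. Its share was 47.6%, 65.3% and 52.0% in the lesions of mouse NK1 and 13.7% to 22.8% in those of NK2.

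The first question was whether transcripts of the transferred cells were present in the captured lesions. NK cell genes were higher in mice with NK cells. Ncr1, which encodes the NK cell receptor NKp46 (chromosome 7, 4337724 to 4345164), had 2.95 ± 0.669 CPM (SD, n = 2 mice) with NK cells and 0.0464 ± 0.0804 CPM (n = 3) in controls. It had 175 counts in 6 of 7 lesions with NK cells, and 5 counts in 2 of 11 control lesions, both from mouse KO1. Gzmb, a granzyme of killer cells (chromosome 14, 56258838 to 56262260), had 414 counts in 6 lesions against 62 counts in 2 lesions of KO1, and its log2 fold change was 3.71 ± 1.78 (SE). Gzma gave 3.68 ± 1.77. Among members chosen after their values were seen, Xcl1, a chemokine of NK cells, gave 4.51 ± 1.30 and the cytokine receptor chain Il2rb 4.53 ± 1.61. The receptor Klra8, also chosen after its values were seen, had 41 counts against 3, a ratio of 19.1 (95% counting interval 6.09 to 96.4) and of 11.7 (3.52 to 60.7) without lesion NK1-1. It is uncertain because other Klra genes resemble it. No member passed the all-gene test in edgeR (adjusted p = 0.9998 for Ncr1), and 0 passed when adjusted over the list alone. Without a filter on low counts, edgeR called Ncr1 (adjusted p = 0.0188), Gzmb (adjusted p = 0.0254) and Gzma (adjusted p = 0.0285). That fit called 224 genes in all, and the simulation did not cover it, so its error rate is not known and these calls are weak evidence. Among the 224 was the fat cell gene Adipoq, chosen after its values were seen, with all its 477 counts in lesion NK1-1.

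As a group, the NK cell marker list rose in the camera test with the preset correlation (adjusted p = 3.59e-13), with a median log2 fold change of 2.34. It did not pass with an estimated correlation (adjusted p = 0.340) or in fry (adjusted p = 0.161). Of its 17 tested members, 15 had positive values and 11 had both NK mice above every control mouse, where chance gives 10% of genes. With a filter of 10 counts in 9 lesions 4 members were tested (median 0.93, camera adjusted p = 0.163). Only 7 lesions came from mice with NK cells, so that filter removes any marker confined to them and cannot test such markers. The list score was 0.91 ± 0.21 log2 CPM (n = 2) with NK cells and -1.50 ± 0.53 (n = 3) in controls. The score of NK1 rested on lesion NK1-1 (1.65), since NK1-2 (-0.60) and NK1-3 (-1.56) lay within the -1.85 to -0.30 of the control lesions. In NK1-2, Ncr1 (4 counts, 1.62 CPM) and Gzma (15 counts, 6.09 CPM) still lay above every control lesion. Gzmb (1 count) and Xcl1 (0 counts) did not. Without NK1-1 the list median was 1.42 over 14 tested members (camera adjusted p = 4.04e-04 with the preset correlation). It did not pass there with an estimated correlation (adjusted p = 0.795) or in fry (adjusted p = 0.949). The members with the highest counts included 2 without such a difference. Klra4 gave 0.74 ± 0.72, and Cd244a, a receptor also carried by other leukocytes, gave -1.78 ± 0.85. Prf1, the pore-forming perforin, gave 0.29 ± 2.01, since 37 of its 38 control counts lay in lesion KO3-2. Klrd1, chosen after its values were seen, gave 2.97 ± 1.06, with 71.0% of its counts with NK cells in lesion NK1-1, and turned to -0.63 without that lesion. Lesion NK1-3 had 0 counts of Ncr1, Gzma and Gzmb, and it was the shallowest library.

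The host genotype gave little to check. Il2rg, the shared cytokine receptor chain that the hosts lack and the transferred cells are assumed to carry, had 138 counts against 55, with a log2 fold change of 1.55 ± 1.04. Rag2 (chromosome 2, 101624718 to 101632529) had 40 counts with NK cells and 81 in controls, and Rag1 had 0 and 1. The tumour cells need not share the host genotype, the deleted parts are not given, and Rag2 lies inside B230118H07Rik on the opposite strand, so these counts check no label.

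**Figure D1:**
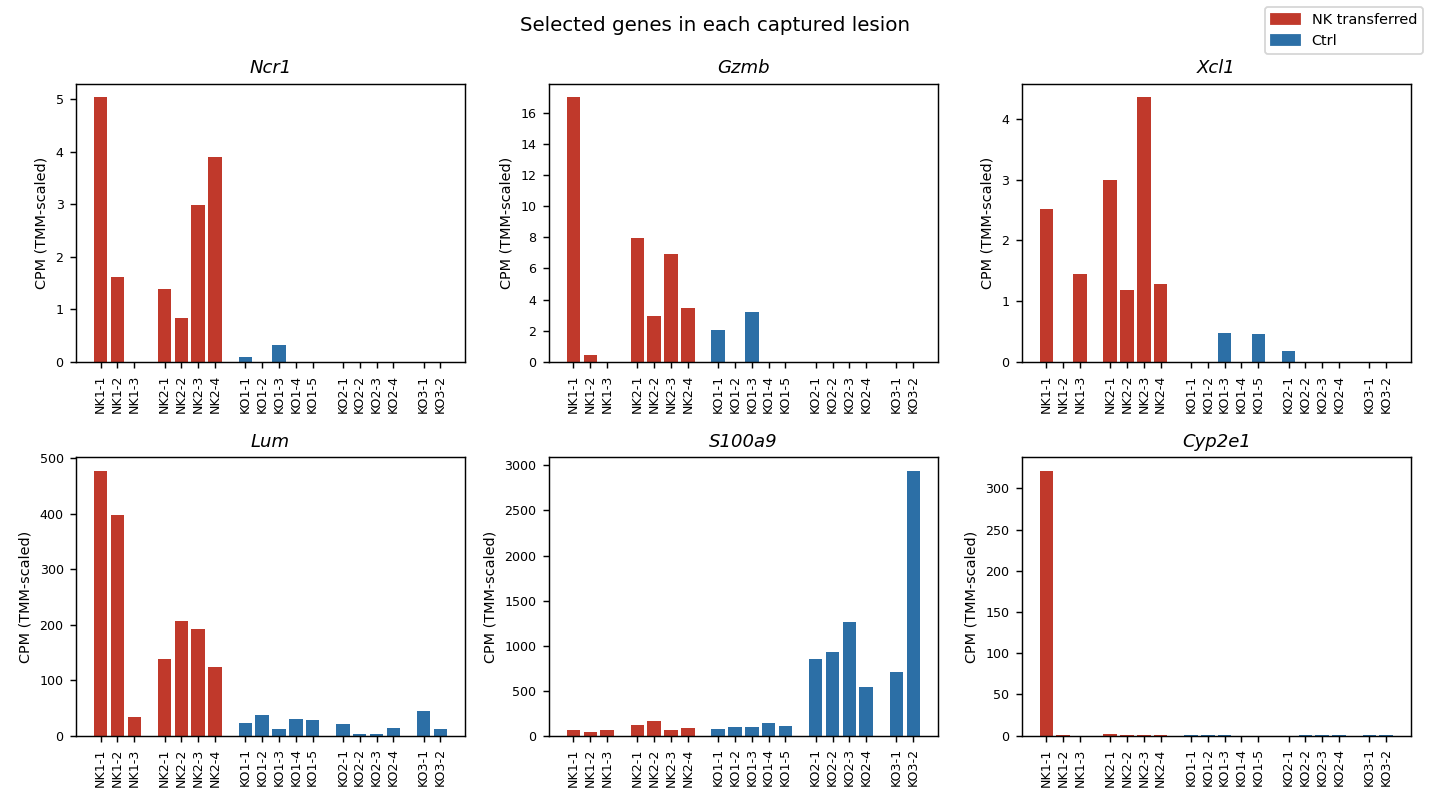
CPM (vertical axes, TMM-scaled, linear from 0) of 6 genes in each of the 18 captured lesions (horizontal axes, grouped by mouse), with red bars for mice with NK cells and blue bars for controls. Ncr1 was seen in 6 of 7 lesions with NK cells, S100a9 was high in mice KO2 and KO3 only, and Cyp2e1 came almost wholly from lesion NK1-1.

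The second question was which genes of the lesion differed between the environments. No gene passed an adjusted p of 0.05 in edgeR, and 426 of 16917 genes (2.52%, where chance gives 5%) had an unadjusted p under 0.05, 262 higher and 164 lower with NK cells. DESeq2 on the same sums, with its own filter, called 39 genes, 27 higher and 12 lower, of which 27 were among the 16917. Limited to those 16917 it called 21, 14 higher and 7 lower. Lum, Col3a1 and Camp were called by DESeq2 in both, and Ncr1 only in the first. Without a filter on low counts edgeR called 224. The genes below are therefore given as not past the threshold.

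Lum, which encodes the collagen-binding protein lumican (chromosome 10, 97565128 to 97572703), had 279 ± 151 CPM (n = 2) with NK cells and 22.1 ± 11.6 CPM (n = 3) in controls, a log2 fold change of 3.66 ± 0.60 with the smallest p of all genes (unadjusted p = 2.85e-04, adjusted p = 0.9998). Dpt, the matrix protein dermatopontin, gave 2.72 ± 0.60, Edil3 3.27 ± 0.68, Lrrc17 3.14 ± 0.64 and C1qtnf6 3.20 ± 0.76. C1qtnf6 had 704 of its 1832 NK group counts in lesion NK1-3 and ranged from 1.47 without that lesion to 4.44 without NK1-1. Edil3 had 359 of 824 in lesion NK1-1 and ranged from 1.47 without it to 3.98 without mouse NK2. Over the same fits, which left out a mouse or a lesion in turn, Lum ranged from 2.97 without mouse NK1 to 4.19 without lesion KO3-1. Dpt ranged from 1.46 without mouse NK1 to 3.39 without NK2, and Lrrc17 from 1.71 without NK1 to 3.93 without lesion KO3-1. Agtr2, a receptor for angiotensin II, had 104 counts in 6 lesions with NK cells and 0 in controls, which makes it at least 48.4-fold higher. Apol6 gave 4.23 ± 1.01, with 1.64 without lesion NK1-1 and 5.0 without mouse NK2. It had 116 of its 224 NK group counts in lesion NK1-1 and 103 in NK2-1, and its median over lesions was 0.0582 CPM with NK cells and 0.233 CPM in controls. A further 3 genes of this set were carried by lesion NK1-1, which held 97.7% of the Cyp2e1 counts, 90.6% of the Myh6 counts and 87.3% of the Slc5a8 counts of the NK group. The fat cell hormone gene Adipoq, chosen after its values were seen, had 477 counts there and 0 in every other lesion.

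On the lower side, Camp, an antimicrobial peptide of neutrophil granules (chromosome 9, 109847379 to 109849617), had 0.458 ± 0.513 CPM (n = 2) with NK cells and 47.6 ± 44.0 CPM (n = 3) in controls, with 1.70 CPM in KO1, 89.4 in KO2 and 51.7 in KO3. Lesion KO2-2 held 3007 of its 4729 control counts. Pi4k2a, a lipid kinase, gave -1.56 ± 0.41, Ccm2l -1.71 ± 0.49, Plxna4 -2.20 ± 0.61, Asprv1 -2.92 ± 0.80 and Ptprr -5.98 ± 1.58. Over the fits that left out a mouse or a lesion, Ccm2l ranged from -1.94 without mouse KO1 to -1.02 without lesion NK1-1, and Plxna4 from -2.97 without mouse NK2 to -1.60 without lesion NK1-1. Ptprr ranged from -10.18 without mouse NK2 to -4.97 without KO2. Gm26735 gave -4.07 ± 1.16, with 518 of 776 control counts in lesion KO2-1 and a median over lesions of 0 CPM in both groups. It ranged from -6.21 without lesion NK1-2 to -2.79 without NK1-1. Gm44321 gave -3.32 ± 0.94, and ranged from -4.16 without mouse NK2 to -2.56 without lesion KO3-1. Zcwpw1 had 3 counts against 192, a ratio of 0.0218 (95% counting interval 0.00446 to 0.0648). Of those 192, 100 lay in lesion KO3-2, without which the ratio was 0.0430 (0.00871 to 0.130). Gm15128 had 2 against 123, a ratio of 0.0227 (0.00272 to 0.0838).

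Of the 21 lists, 7 passed camera with the preset correlation, 4 higher and 3 lower with NK cells, and 0 passed with an estimated correlation or in fry. The matrix list rose (median 0.43, mean 0.72, camera adjusted p = 0.00250, and adjusted p = 0.740 with an estimated correlation). Its score was 5.37 in NK1, 5.17 in NK2, 5.01 in KO1, 4.15 in KO2 and 4.25 in KO3, so that KO1 lay nearer to the mice with NK cells than to the other controls. Of its 20 members 14 were positive, 7 had both NK mice above all controls, and 3 passed when adjusted over the list alone, Lum, Col3a1 and Col6a3, against 0 over all genes. Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), gave 3.32 ± 0.81, with 53.5% of its NK group counts in lesion NK1-1, and Col6a3 2.47 ± 0.60. Dcn gave 1.28 ± 0.74 and Sparc 0.56 ± 0.51. Col1a1 gave -0.40 ± 0.85, and 1.13 without mouse KO1. Col6a3 and Col1a1 were chosen after their values were seen. The list was not past the threshold without mouse NK2 (adjusted p = 0.102), and its median was 0.23 without lesion NK1-2, 0.69 without lesion KO3-1 and 1.10 without mouse KO1. The muscle list rose as well (median 1.31, adjusted p = 9.42e-04, and adjusted p = 0.740 with an estimated correlation), with 13 of 14 members positive and 1, Myh6, past the test when adjusted over the list alone. Its score was 3.42 in NK1 and 0.67 in NK2, against 0.16 to 0.88 in the controls. It turned to -0.25 without lesion NK1-1, passed as lower at -0.46 without lesions NK1-1 and NK1-3 (adjusted p = 0.0146), and was not past the threshold without mouse NK1 (adjusted p = 0.435). Acta2, a smooth muscle actin, gave 0.51 ± 0.44, Tagln 1.06 ± 0.53 and Mylk -1.07 ± 0.67.

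Neutrophil genes fell as a group (median -2.33, camera adjusted p = 1.83e-11, and adjusted p = 0.740 with an estimated correlation), with 16 of 19 members negative and 7 past the test when adjusted over the list alone. S100a9 (chromosome 3, 90692632 to 90695721), a subunit of the abundant neutrophil protein calprotectin, had 82.0 ± 38.3 CPM (n = 2) with NK cells and 867 ± 726 CPM (n = 3) in controls. S100a8 gave -2.93 ± 0.93 and the gelatinase gene Mmp9 -2.30 ± 0.73. The remaining 4 of the 7 were Camp and, chosen after their values were seen, Csf3r at -2.26 ± 0.65, Ngp at -3.14 ± 0.97 and Retnlg at -3.50 ± 1.11. The control mice were not alike. The list score was 1.09 in NK1, 2.35 in NK2, 2.24 in KO1, 4.64 in KO2 and 4.85 in KO3, so that KO1 lay among the mice with NK cells. The median was -3.94 without mouse NK2. The red blood cell list also fell (median -1.57, adjusted p = 0.00667, and adjusted p = 0.812 with an estimated correlation), with 8 of 8 members negative and 0 past over the list alone. Its score was 3.54 in NK1, 4.42 in NK2, 3.23 in KO1, 6.67 in KO2 and 5.76 in KO3, so that KO1 was the lowest of the 5 mice. Hbb-bs gave -1.57 ± 0.96, Hba-a1 -1.34 ± 0.82 and Hba-a2 -1.63 ± 0.82, and these copies resemble each other. The list was not past the threshold without mouse NK1, NK2, KO2 or KO3, or without lesion KO3-2, with a median of -0.79 without KO2 (adjusted p = 0.314).

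Endothelial genes fell as a list (median -0.70, camera adjusted p = 2.48e-06, and adjusted p = 0.812 with an estimated correlation), with 19 of 20 members negative and 0 past over the list alone. The score was 1.63 log2 CPM in NK1, 4.22 in NK2 and 3.83, 4.42 and 4.06 in the controls, and the median turned to 0.08 without mouse NK1. Cdh5, the cadherin of vessel walls, gave -0.38 ± 0.86, Calcrl -0.45 ± 0.95 and Ptprb -0.41 ± 1.03. The lesions of NK1 also had a high mt-Rnr2 share, as did control lesions KO1-2 (58.3%), KO1-5 (68.7%) and KO3-2 (44.05%). The surfactant gene Sftpc of alveolar cells had 73.9 CPM in NK1 and 777 CPM in NK2.

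The interferon response list rose (median 0.35, camera adjusted p = 0.0324, and adjusted p = 0.812 with an estimated correlation), with 21 of 29 members positive and 0 past over the list alone. Its score was 3.54 in NK1, 3.75 in NK2, 3.33 in KO1, 3.69 in KO2 and 2.44 in KO3. Irf9, a transcription factor of interferon signalling, gave -0.30 ± 0.38 and Rsad2 -0.54 ± 0.77. Cxcl9, a chemokine induced by interferon gamma and chosen after its values were seen, had 399 counts against 34, of which 282 lay in lesion NK2-1. The list was past the threshold in 12 of 23 fits that left out a mouse or a lesion. It was not without mouse NK1, NK2, KO1 or KO3 or without lesion NK1-3, NK2-1, KO1-3, KO1-4, KO2-2, KO2-4 or KO3-1, and its median was -0.17 without lesions NK1-1 and NK1-3.

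**Figure D2:**
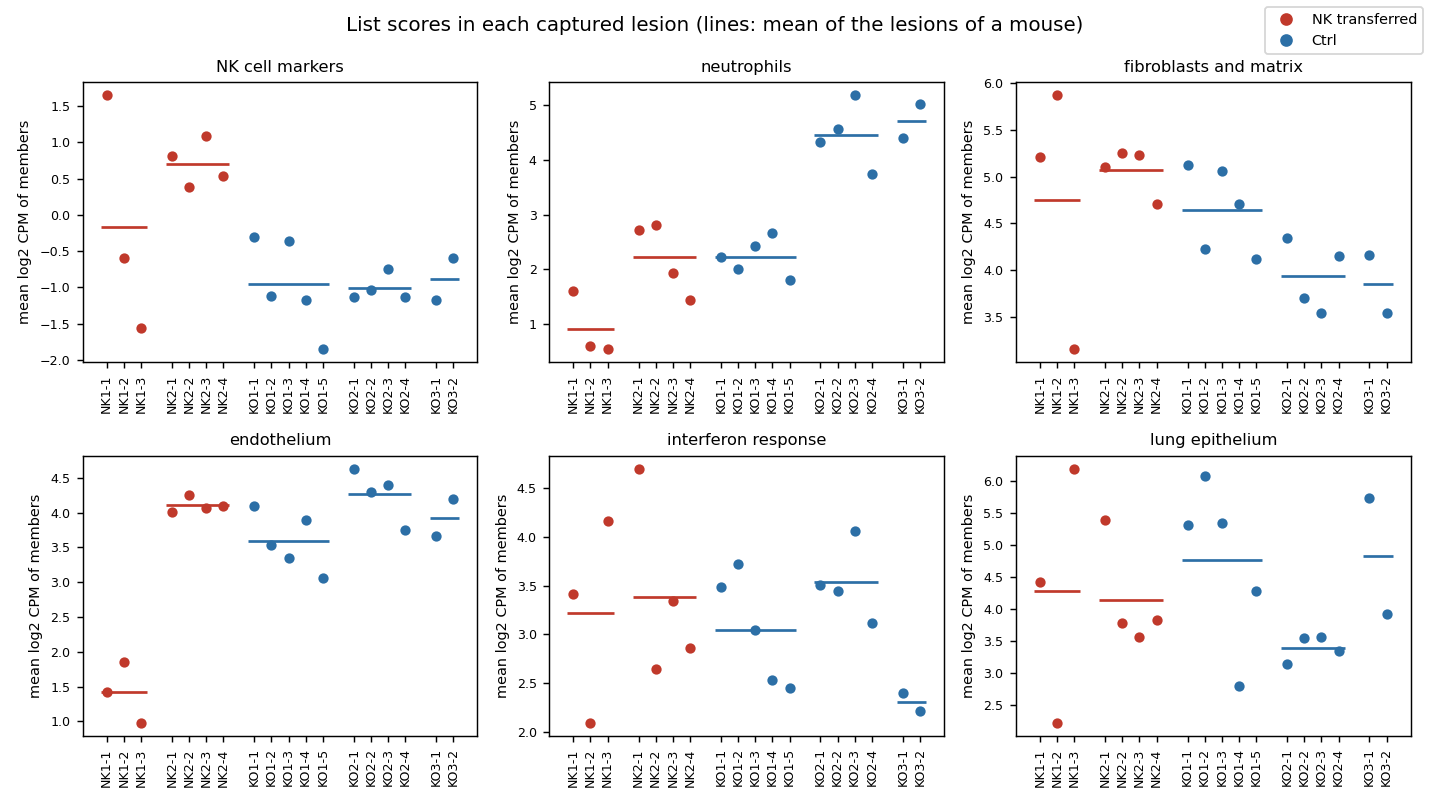
Mean log2 CPM of the tested members (vertical axes) of 6 gene lists in each of the 18 lesions (horizontal axes), with red points for mice with NK cells, blue points for controls and a line at the mean of each mouse's lesions. Neutrophil scores of KO1 overlap those of mice with NK cells, and the endothelial scores of NK1 (0.98 to 1.85) lie below those of every other lesion.

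The other primary lists did not pass. Ligands of activating NK cell receptors had a median of -0.23 (4 of 12 positive, adjusted p = 0.604), with Clec2d, a ligand of inhibitory Nkrp1 receptors, at 0.09 ± 0.54, Pvr at -0.47 ± 0.57 and Icam1 at -0.67 ± 0.65. Clec2d turned to -1.09 without lesion NK1-1 and to -0.74 when each lesion had the same weight. MHC class I genes had a median of 0.26 (15 of 20 positive, adjusted p = 0.106), with H2-K1 at 0.14 ± 0.38, H2-D1 at -0.14 ± 0.39 and B2m at 0.24 ± 0.38. The list passed in several alternatives, with adjusted p = 0.0274 in the normalized table and adjusted p = 0.0117 with the mouse as a random block, and also without mouse NK1 (0.43) or KO2 (0.50) or lesion NK1-1 (0.32). These passes rest on the preset correlation, and with all lesions the list had adjusted p = 0.812 with an estimated correlation and adjusted p = 0.907 in fry. Epithelial keratins and junctions had a median of 0.39 (16 of 26 positive, adjusted p = 0.418). The highest scores of this list, 4.85 in NK1-3 and 3.35 in KO3-1, lay in lesions with lung epithelium scores of 6.19 and 5.74. Lesion KO1-2, with a lung epithelium score of 6.07, had 2.64. The list therefore cannot tell epithelial genes of tumour cells from captured lung epithelium. Krt18 gave -0.71 ± 0.41 and Tjp1 0.41 ± 0.46, while Cdh1, the epithelial cadherin, gave -0.64 ± 0.65 and Epcam 0.51 ± 0.74. Krt14 had 2 counts with NK cells and 0 in controls, which allows at most 0.0323 CPM in the latter. The epithelial list passed as higher when each lesion had the same weight (adjusted p = 0.00321) and without lesion NK1-1 (0.71) or KO3-1 (0.96). These passes rest on the preset correlation, and with all lesions the list had adjusted p = 0.812 with an estimated correlation and adjusted p = 0.907 in fry. Its median was 0.92 without mouse NK2. It was -0.73, and so lower, without the 6 lesions with over 40% of counts in mt-Rnr2, which also left mouse NK2 alone. Mesenchymal transition genes had a median of -0.06 but a mean of 0.08 and an upward camera direction (7 of 20 positive, adjusted p = 0.748). With all lesions the list had adjusted p = 0.896 with an estimated correlation and adjusted p = 0.907 in fry. Its median was 0.35 without mouse NK1, which left NK2 alone in its group. Vim gave -0.14 ± 0.49, S100a4 -0.68 ± 0.41 and the matrix protein fibronectin, Fn1, 1.03 ± 0.40.

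**Figure D3:**
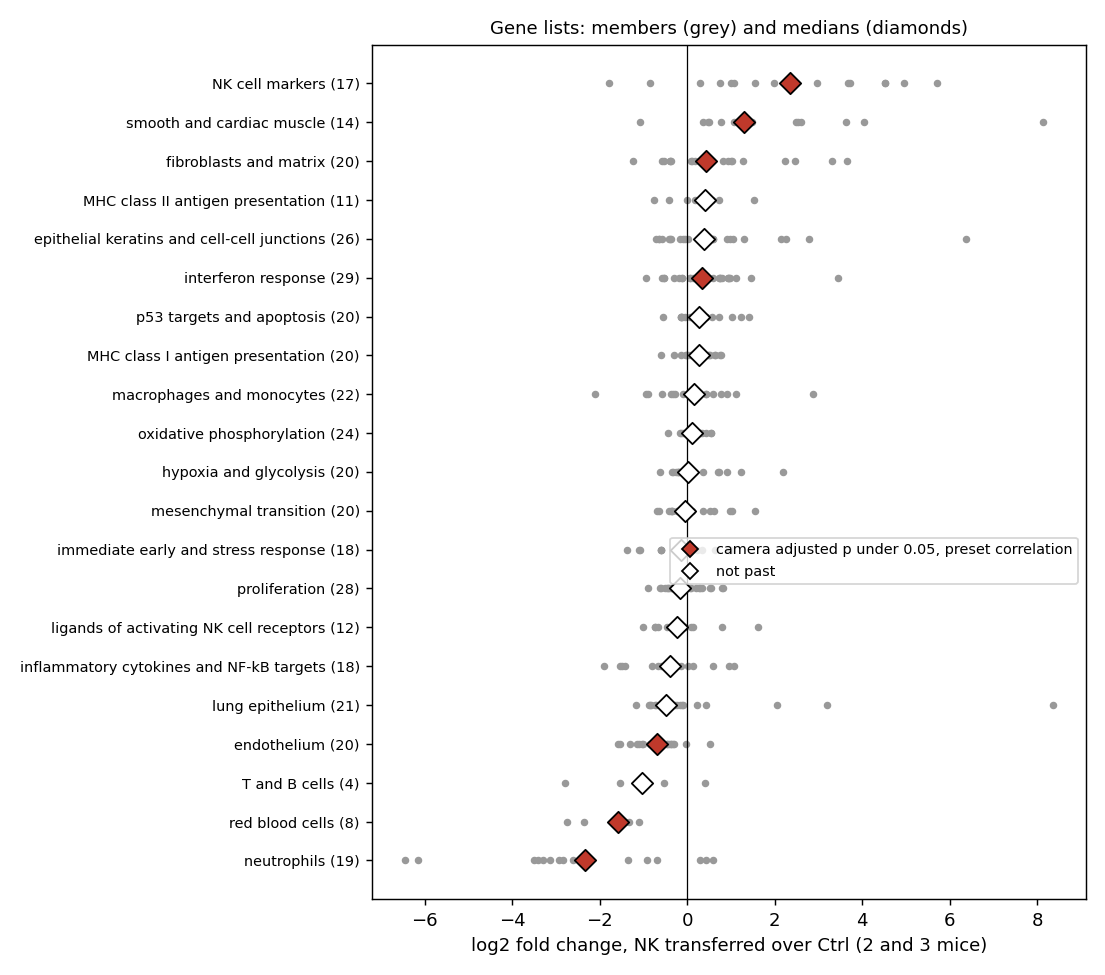
Log2 fold change between mice with NK cells and controls (horizontal axis) of the members (grey points) and the median (diamonds) of each of the 21 lists (vertical axis, number of tested members in brackets), red where camera passed with the preset correlation. NK cell markers have the highest median at 2.34 and neutrophils the lowest at -2.33.

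The remaining 10 lists did not pass either, and 0 of their members passed over the list alone. Any pass named below, in a fit that left out a mouse or a lesion, rests on the preset correlation. With all lesions 0 lists passed with an estimated correlation or in fry. MHC class II genes had a median of 0.41 (adjusted p = 0.463), but 0.93 without mouse NK1 and -0.73 without mouse NK2, with Cd74 at -0.00 ± 0.69, H2-Aa at 0.48 ± 0.57 and Ctss at 0.73 ± 0.61. Macrophage genes had 0.16 (adjusted p = 0.687), but passed without mouse NK1 (0.24, adjusted p = 0.0386), with Lyz2 at 0.23 ± 0.48, C1qc at 0.14 ± 0.52 and Chil3 at -0.58 ± 1.06. Lung epithelium had a median of -0.48 but a mean of 0.26 (adjusted p = 0.434, direction down) and passed as lower without mouse KO2 (-0.50, adjusted p = 0.0331), with Sftpc at -0.50 ± 0.83, Sftpa1 at -0.11 ± 0.65 and the airway secretoglobin Scgb1a1 at -0.82 ± 2.26. T and B cell genes had -1.03 over 4 tested members (adjusted p = 0.512), with Cd4 at -2.78 ± 1.87, Cd79b at -0.53 ± 0.99 and Ighm at 0.40 ± 0.65. Proliferation had -0.16 (adjusted p = 0.693), with Mcm7 at -0.41 ± 0.52, Mcm3 at -0.50 ± 0.39 and Ube2c at -0.34 ± 0.64. Hypoxia and glycolysis had 0.03 (adjusted p = 0.519), with Gapdh at -0.33 ± 0.51, Ldha at 0.04 ± 0.47 and Tpi1 at -0.04 ± 0.44. The p53 list had 0.26 (adjusted p = 0.286), with Ccng1 at 0.73 ± 0.60 and Mcl1 at -0.15 ± 0.37. Inflammatory cytokines had -0.39 (adjusted p = 0.122) and passed as lower without mouse NK2 (-1.01) or KO1 (-0.47) or lesion NK1-2 (-0.50) or KO3-1 (-0.52), with Nfkb1 at -0.42 ± 0.40 and Csf1 at -0.49 ± 0.52. Immediate early genes had -0.15 (adjusted p = 0.317), with Hsph1 at -0.24 ± 0.34, Dusp1 at -0.17 ± 0.52 and Ier2 at -0.60 ± 0.43. Oxidative phosphorylation had 0.11 (adjusted p = 0.317) and passed without mouse KO2 (0.35, adjusted p = 0.0103), with Cox4i1 at 0.17 ± 0.36, Atp5a1 at 0.22 ± 0.44 and Atp5b at 0.10 ± 0.51.

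The last comparison asked whether lesions of a host resembled each other. The mean Pearson correlation of log2 CPM was 0.862 between lesions of the same mouse and 0.790 between mice with NK cells. The difference of 0.072 had a one-sided exact permutation p of 0.0286, the smallest that 35 arrangements can give. In controls the values were 0.882 and 0.843, a difference of 0.039 (one-sided exact permutation p = 0.00303 over 6930 arrangements). Within mouse NK1 the pairs reached 0.661 to 0.8, below the 0.927 to 0.958 of NK2, and the NK1 pairs with NK1-3 (0.661 and 0.684) lay below the mean between mice. So did the single pair of KO3, at 0.782 against 0.843, and 3 pairs of KO1, each with lesion KO1-5 (0.814, 0.815 and 0.839). The group means therefore do not hold for every pair or host.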

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

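All tests of explanations in this part were chosen after the results were seen. A lesion was singled out where it lay far from the other lesions of its group by Dixon's criterion. By a rule fixed beforehand, groups of over 10 were not tested, so that the 7 lesions with NK cells were searched and the 11 control lesions and the mice were not. A lesion as far apart among the controls would not be listed here. Of 34 groups of values tested, 9 held such a lesion. Chance gives about 1 in 20, or 1.7, for independent values, but these lesions come from 2 mice that differ, so 1.7 is no valid comparison for the 9.

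Lesion NK1-3 accounted for 7 of the 9. Its score of mesenchymal genes was 1.72 log2 CPM (other lesions 4.27 to 5), of proliferation 3.69 (5.30 to 5.82), of macrophages 2.13 (3.65 to 4.65) and of matrix genes 3.16 (4.71 to 5.87). It had 215.3 CPM of Cdh1 (others 0.406 to 52.9), 93.61 CPM of Epcam (1.62 to 22.4) and 8.641 CPM of Rag2 (0 to 0.7995). The Rag2 value rests on 12 counts, and B230118H07Rik, which overlaps Rag2 on the opposite strand, had 7.20 CPM there. Lesion NK1-3 also had the fewest counts of all lesions (2964242), with 52.0% of them in mt-Rnr2. Its lung epithelium score was the highest of all lesions (6.19), with 21950 CPM of Scgb1a1. Its Cdh1 and Epcam values therefore cannot be told apart from captured lung epithelium. Lesion NK1-1 had a muscle score of 4.01 (others -0.89 to 1.10). Lesion NK1-2 had 0.8118 CPM of Krt14, which is 2 counts, against 0 in the others.

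Endothelial genes were lower in mouse NK1 than in the other 4 mice. A high share of mt-Rnr2 counts as the whole explanation is argued against by control lesions KO1-2 and KO1-5. Their shares were 58.3% and 68.7%, yet the lower of their endothelial scores lay 1.21 above the highest NK1 lesion, against an SD of 0.36 between lesions of a mouse. Less alveolar tissue in the captured area stays a candidate explanation. The 14 alveolar genes of the lung epithelium list had a median of -1.72 in NK1 relative to the mean of the other mice, with 12 below 0, although the 6 airway genes had 4.02, and a difference due to NK cells in this host was not tested.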

How the results depend on the processing

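The fits with DESeq2 on the genes kept by the filter, without ribosomal RNA genes, without the 6 lesions with over 40% mt-Rnr2, and without lesions NK1-1 and NK1-3 were chosen after seeing the data. A gene's change of sign counts as reversed where the alternative passes the threshold or the estimate moved by over its SE, and a list's where either setting is past the threshold. Where not stated otherwise, the cause was not tested. Named genes were reversed in 31 of their leave-one-out values (2231 kept their call, 1 became past the threshold) and in 30 of their other alternatives (1264 kept it, 63 became past it). The median of all genes moved by over 0.1 only without mouse NK2, to -0.16. Where a group is left with 1 mouse, that mouse is assumed to vary like the others. Low counts limit the NK cell list, with 17 of 26 members tested, and the T and B cell list, with 4 of 19. Of those 17 NK cell genes 4 had 10 counts in 9 lesions, which genes confined to the 7 lesions with NK cells cannot reach.

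The number of genes past the threshold was 0 with size factors of DESeq2, without ribosomal RNA genes, without the 6 lesions, without lesions NK1-1 and NK1-3, and with the filter of 10 counts in 9 lesions, equal weight per lesion, the mouse as a random block, the normalized table and a threshold of 0.1. It was 224 without a filter on low counts (140 higher, 84 lower, 175 of them among the genes tested with the filter), 39 with DESeq2 and its own filter (27 higher, 12 lower, 27 of them among the genes tested in edgeR), 21 with DESeq2 on the genes tested in edgeR (14 higher, 7 lower) and 2 with lesions as replicates (Lum and Lrrc17), where p-values are too small. Leaving out a mouse or lesion gave 0 to 4, with 4 without NK2. The number of lists was 7 to 10 in the other alternatives, 5 to 9 over the leave-one-out fits, and 0 with an estimated correlation and in fry. Lesions of the same host were on average more alike than those of different hosts in both alternatives, though not in every host (differences 0.340 and 0.072 with NK cells, 0.192 and 0.040 in controls).

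With host number as a replicate block, 7 genes passed (6 higher and 1 lower) and 9 lists. The labels do not tie equal numbers to a shared litter or day. Deviations correlated at 0.10 for the hosts numbered 1 and 0.29 for those numbered 2, and 2 pairs are too few to pair by. Under this block the interferon list was at 0.12 and not past the threshold, the epithelial list at 0.66 and past it, and Cdh1 0.18, Pvr 0.26 and Scgb1a1 5.11 were reversed.

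The NK cell list was at 2.34 and the interferon list at 0.35 with an estimated correlation and in fry, both not past the threshold. In camera only the correlation setting changed, from 0.01 to 0.115 for the NK cell and 0.33 for the interferon list. For fry the cause was not tested. The NK cell list was at 0.93 with the filter of 10 counts in 9 lesions. Fewer members are tested there, since that filter removes genes confined to lesions with NK cells. The interferon list was also not past the threshold at 0.26 with equal weight per lesion, 0.30 with lesions as replicates, 0.15 with the mouse as a random block and 0.13 without the 6 lesions. The MHC class I list passed at 0.28 with the stricter filter, 0.33 with lesions as replicates, 0.30 with the random block without and with the covariate, 0.22 in the normalized table and 0.40 without the 6 lesions. The epithelial list passed at 0.63 with equal weight and 0.36 in the normalized table. Lesions as replicates reversed Cdh1 (0.21), Irf9 (0.08) and Rag2 (0.86). Clec2d was reversed at -0.74 with equal weight, -0.50 with the random block without and with the covariate, and -0.55 in the normalized table.

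Without the 6 lesions, which leaves NK2 alone, the epithelial list was at -0.73, opposite in sign to its 0.39 with all lesions. The mesenchymal list was at 0.33 and the endothelial list at 0.19. For these lists only medians are given, since 1 mouse cannot show the spread of its group. Reversed genes were Cd74 0.71, Chil3 0.49, Clec2d -0.90, Csf1 0.32, Epcam -0.78, Gapdh 0.23, H2-D1 0.33, Icam1 0.07, Ighm -0.76, Pvr 0.48, Sftpc 0.59, mt-Rnr2 -0.92 and B230118H07Rik -0.21. Without lesions NK1-1 and NK1-3 the interferon list was at -0.17 and not past the threshold, while the muscle list was at -0.46 and past it as lower (adjusted p = 0.0146), opposite to its rise with all lesions. Clec2d -0.86, Epcam -1.10, H2-K1 -0.32, Tagln -0.03, Tjp1 -0.06, Klrd1 -0.53 and B230118H07Rik -0.14 were reversed.

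Over the fits that leave out a mouse or lesion, list medians ranged from 0.13 to 0.50 for MHC class I, 0.11 to 0.83 for interferon, -0.52 to 0.96 for epithelial, -0.80 to 0.35 for mesenchymal, -2.77 to 0.08 for endothelial, -0.25 to 2.48 for muscle, 0.23 to 1.10 for matrix, -2.06 to -0.79 for red blood cell, 1.42 to 3.14 for NK cell and -3.94 to -1.98 for neutrophil genes. They were -0.73 to 0.93 for MHC class II, -1.01 to -0.04 for inflammatory, -0.27 to 0.29 for macrophage, -0.69 to -0.04 for lung epithelium and -0.09 to 0.35 for oxidative phosphorylation genes. Genes with a reversed value ranged as follows, in log2: Atp5b -0.62 to 0.58, C1qc -0.80 to 0.71, Cd74 -1.86 to 0.78, Cdh5 -2.95 to 0.48, Clec2d -1.09 to 0.68, Csf1 -1.53 to 0.11, Ctss -0.66 to 1.43, Epcam -0.45 to 1.2 and Gapdh -1.32 to 0.25. Further ranges were H2-Aa -0.80 to 1.15, Icam1 -2.34 to 0.08, Ighm -0.59 to 1.10, Irf9 -0.52 to 0.12, Klra4 -0.14 to 1.34, Ldha -0.48 to 0.43, Pvr -1.33 to 0.35, Rsad2 -1.17 to 0.58, Scgb1a1 -2.75 to 1.61 and Sftpa1 -1.74 to 0.65. The rest were Sftpc -3.03 to 0.37, Tagln -0.05 to 1.59, Ube2c -1.19 to 0.35, mt-Rnr2 -1.38 to 1.34, Klrd1 -0.63 to 3.87, Cxcl9 -1.73 to 4.41, Col1a1 -0.81 to 1.13 and B230118H07Rik -0.25 to 1.21.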

Other observations

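All tests of explanations in this part were chosen after the results were seen, and Cma1, Adipoq and Il2rb were chosen after their values were seen. Cma1, a mast cell chymase (chromosome 14, 55941451 to 55944675), had 131 counts in lesion NK1-1, 160 in NK1-2, 27 in NK2-4 and 2 each in NK2-1 and NK2-2, with 0 in the 11 control lesions. Over the groups, with 322 counts against 0, it was at least 150-fold higher with NK cells. Lesion NK1-1 held 477 counts of the fat cell gene Adipoq (chromosome 16, 23146536 to 23158028) beside 299 counts of the heart muscle gene Myh6. Scgb1a1, a secretoglobin of airway cells, ranged from 0.218 CPM in NK2-3 to 21950 CPM in NK1-3 and 15100 CPM in KO3-1.

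Counts of NK cell genes were also found in a host labelled as control. Lesions KO1-1 and KO1-3 of a control host held 23 and 38 counts of Gzma, 21 and 41 of Gzmb, 6 and 4 of Il2rb and 1 and 4 of Ncr1, while the lesions of KO2 and KO3 held 0 of these 4 genes. Other members of the list were not confined to KO1 among the controls. Prf1 had 37 counts in KO3-2 and 1 in KO1-1. Klrd1 had 10 to 36 counts in the lesions of KO2, against 0 to 8 in those of KO1. For the NK cell list, 2 of the 10 splits of the 5 mice into 2 and 3 had a median as far from 0 as the real 2.34, and the highest other was 2.55 in size, for KO1 with KO2 against the rest. That split keeps NK1 and NK2 together and so restates their difference from these controls. The 6 splits that part NK1 from NK2 had medians of -0.16 to 0.85 and 0 of them passed (adjusted p from 0.133 to 0.757 in camera). The number of lists past the threshold was 7 for the real split, 5 of the 10 splits gave as many, and the highest other was 10. With 10 splits the share is never under 0.05, so these checks are too small to decide. Carry-over of reads from the lesions with NK cells is argued against by Lum. Those with more Gzmb than KO1-3 held 1899 to 3030 counts of Lum, against 160 in KO1-3 and 230 in KO1-1. A share of their reads large enough to bring 41 counts of Gzmb would bring more Lum than that. Other sources of carry-over and other explanations were not tested for the counts in KO1, so these counts do not show NK cells in that host.

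Neutrophil genes were lower in mice with NK cells, with control mouse KO1 at the level of NK2. A high share of mt-Rnr2 as the whole explanation is argued against by KO2 and NK2, whose shares overlap: the lowest KO2 lesion score lay 0.94 above the highest NK2 lesion score, against an SD of 0.54 between lesions of a mouse. Of the 10 splits of the 5 mice, 3 had a median as far from 0 as the real -2.33, the highest other at 2.96 in size for NK1 with KO1 against the rest, but 10 splits are too few to decide. The other splits as far from 0 put KO1 with NK1 or with both NK mice, so they restate that KO1 scored low. Differences between hosts apart from the transfer and an effect of the transfer both stay open.

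Matrix genes were higher in both mice with NK cells (scores 5.37 and 5.17), but control KO1 lay close at 5.01, against 4.15 in KO2 and 4.25 in KO3. The list median did not rest on lesion NK1-1 alone, at 0.51 without it and 0.43 with all lesions. Without it the list passed camera with the preset correlation. It did not with an estimated correlation (adjusted p = 0.795) or in fry (adjusted p = 0.949), as was so with all lesions (0.740 and 0.907). The preset pass decides nothing, since the split of NK2 with KO1 against the rest passed as well (camera adjusted p = 0.0260). In NK1, 19 of 20 endothelial and 12 of 14 alveolar genes lay below the mean of the other mice, which argues against more alveolar tissue there. Its 6 airway genes were higher (median 4.02). More airway tissue in NK1, more host lung tissue in NK2 and a difference due to NK cells all stay open. The matrix score minus the endothelial score was 3.74 in NK1 and 0.95 in NK2, against -0.27 to 1.18 in the controls, so NK2 alone lay within the control range. Of the 10 splits, 3 had a median as far from 0 as the real 0.43, the others being 0.60 for NK1 with KO1 and, the highest at 0.85 in size, -0.85 for KO2 with KO3 (camera adjusted p = 3.75e-04), which keeps NK1 and NK2 together, and 10 splits are too few to decide.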
